A study of Arabidopsis thaliana with 33 samples.

How the data were processed

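RNA was sequenced from hypocotyls of 33 libraries in 11 groups of 3, each library a pool of 5 hypocotyls. The libraries were made with a stranded mRNA kit and read as pairs of 101 cycles, per the labels' protocols. The deposited values are whole-number read counts per gene, made by the authors with STAR's gene counting, per the file layout and the submitters' processing notes. Those notes also name CASAVA 1.8.3, FastQC 0.11.3 and the TAIR10 genome. The version of STAR and the gene annotation are not given in the sources used here.

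Each file holds unstranded, antisense and sense counts, of which the sense column was used. Sense counts were 48.3 to 60.9 times the antisense counts, which were 1.62 to 2.03% of the total. Unmapped reads were 4.36 to 16.3%, multimapping reads 1.06 to 1.44%, reads outside genes 0.786 to 1.36% and ambiguous reads 0.853 to 1.26%. These 4 classes name no gene and stayed out of library sizes and tests. Reads that map to several places are not counted, so genes with near-identical copies, such as those of the antenna proteins, rubisco and the small heat shock proteins, have uncertain levels. Organelle genes took 0.0109 to 0.0234% of the counts and the 20 most abundant genes 5.16 to 7.70%.

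Gene names came from a table of the TAIR10.1 assembly by locus tag, which matched 32835 of 33602 genes. Since the builds differ by name, no coordinates are printed. Symbol and code disagreed for GXM1 and GXM3, which were left out of the xylan list.

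Genes were filtered with filterByExpr, which left 19833, scaled with TMM and fitted with edgeR's robust quasi-likelihood model over all 33 libraries, with 1 term per group. Adjusted p-values are Benjamini-Hochberg values from this model, two-sided, with a threshold of 0.05. The 18 results are 6 later days against day 0 in the induced line, 3 in the control line, the lines at 4 days, 3 interactions and 2 F tests over several days. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used. Log2 CPM for correlations and principal components used a prior count of 2. A fold against a group without counts is a lower bound from a floor of 3 counts over the group, and a group with 1 to 3 counts is given a pooled ratio with a 95% interval. Floors and intervals cover counting error only. No exact permutation test of 3 against 3 libraries can give a p under 0.1.

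The 27 gene lists were flowering regulators, floral organ markers, secondary wall regulators, secondary wall repressors, secondary wall cellulose, primary wall, xylan, lignin, vessel cell death, cambium, cell division, phloem, periderm and suberin, photosynthesis, root hair, ABA synthesis and turnover, ABA receptors and kinases, ABA response, gibberellin, auxin, cytokinin, jasmonate, salicylate, heat shock, senescence, flavonoid and circadian clock. Of 386 members written, 351 were measured. Each list was tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. Of 432 such tests, 147 passed, and 24 of these passed with an estimated correlation too.

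Genes are named by a rule with 3 parts. The first is a panel of 30 genes of flowering, fibres, walls, cambium and hormones, of which 27 were measured. The next is the 6 largest rises and 6 largest falls of a comparison, with a mean log2 CPM of at least 1 and, outside interactions, no overlap between replicates. The last is up to 4 members of each list with the smallest p in a comparison. From these the text gives a selection made after their values were seen, which mostly leaves out genes whose call rested on 1 library or setting. Groups, tests, lists, the naming rule and the alternatives were fixed before the data were examined, except where the text says otherwise.

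The fit was tested on simulated counts for induced day 4 against day 0 over 19610 genes. It recovered 89 of 100 genes changed 2-fold (median estimate 0.99) and 97 of 100 changed 4-fold (2.01), and called 10 unchanged genes. The list of changed genes was called and none of 25 unchanged. Genes were independent and not split by level, and few changed, so correlated lists, low counts and many changes stay open.

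The alternatives were RLE and upper quartile scaling, DESeq2, no filter, a filter of 1 CPM in 3 libraries, the unstranded column, nuclear genes only, a replicate term, only the groups compared, and leaving out each library in turn. Control libraries of days 2, 6 and 14 were not analysed here. Every induced library after day 0 had both the fusion and dexamethasone and every control library had neither, so the effects of line and dexamethasone cannot be separated.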

Results

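Transcript levels were measured by RNA sequencing in the hypocotyl of Arabidopsis thaliana, the stem base in which xylem first forms vessels and later, after flowering, fibres with thick secondary walls. The series follows this change of xylem phase and the part that abscisic acid (ABA) plays in fibre formation. An inducible line carried CONSTANS (CO), a regulator that promotes flowering in long days, fused to the glucocorticoid receptor domain behind the 35S promoter, in a co-2 tt4 background that lacks working CO (AT5G15840) and chalcone synthase. Dexamethasone lets such a fusion protein enter the nucleus. Plants of this line were given 25 ml of 10 µM dexamethasone at 6 weeks and hypocotyls were collected on day 0, on each of days 1 to 4, and on days 6 and 14. Control plants (co-2 tt4, without the fusion) received water and were collected on days 0, 1, 3 and 4. Each of the 11 groups, called induced or control with the day, had 3 libraries of 5 pooled hypocotyls, 33 libraries in all. The labels do not say whether the day 0 plants of the induced line were collected before the dexamethasone was given.

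The libraries held 6288579 to 18574891 read pairs assigned to genes, with a median of 13065647. Comparisons used the 19833 genes that passed the count filter. Changes are log2 fold changes ± SE, levels are CPM (counts scaled to library size, mean ± SD), and n = 3 libraries in every group. Nothing in the labels says that the pools of a group came from separate sowings, so the p-values measure the spread between these libraries. For a gene list, genes up or down refer to the measured members tested singly, the others not having passed, and the adjusted p in the same bracket is that of the list as a set (camera). Replicates correlated across genes at 0.971 to 0.991 on the log2 CPM scale. The first principal component held 34.2% of the variance and the next 22.1%. All control libraries and induced day 0 lay between -50.3 and -29.4 on the first, induced days 1 to 4 between -4.30 and 32.2, day 6 between 43.7 and 49.9, and day 14 between 90.4 and 99.6. Replicate 1 of induced day 2 and replicate 3 of induced day 3 stood apart from their groups on the next component, at -15.1 against -42.0 and -44.8, and at -14.2 against -38.1 and -35.5.

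**Figure D1:**
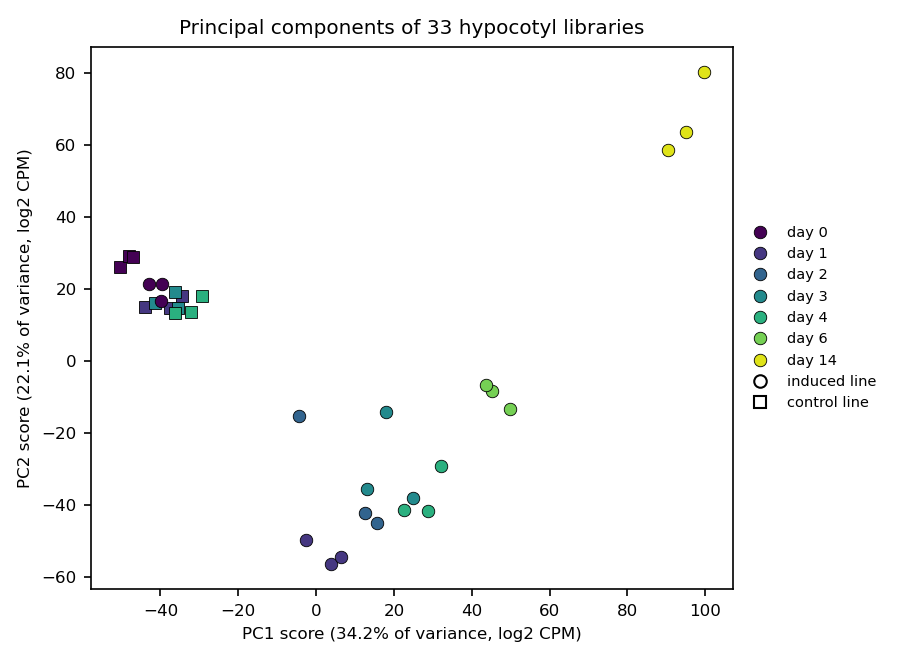
Principal components of log2 CPM for the 33 libraries, each point 1 library, coloured by day, with circles for the induced line and squares for the control line. Induced day 14 lies alone at 90.4 to 99.6 on the first component.

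CO was examined first in every group, since it checks the labels. CO transcripts stood at 769.9 ± 134 CPM in induced day 0 and 1265 ± 136 CPM at day 1, against 3.57 ± 1.34, 0.842 ± 0.0766, 0.965 ± 0.0527 and 1.33 ± 1.06 CPM in the control line on days 0, 1, 3 and 4. These counts include the fusion transcript, which the 35S promoter makes without dexamethasone. In the induced line the difference in CO between day 0 and day 1 did not pass the test (log2 0.72 ± 0.29, adjusted p = 0.0526). It passed with only the libraries compared (0.72, adjusted p = 0.0051), the unstranded column (0.71, adjusted p = 0.0435), a filter of 1 CPM in 3 libraries (0.72, adjusted p = 0.0488), RLE size factors (0.72, adjusted p = 0.0498) or without induced day 0 replicate 2 (0.85, adjusted p = 0.0468).

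The early response was read from induced day 1 against induced day 0. FT (AT1G65480), the mobile flowering signal that CO switches on, had no counts in the day 0 libraries and rose to 21.6 ± 5.11 CPM, at least 363-fold higher by a floor of 3 counts over the group. Its close relative TSF (AT4G20370) rose by a pooled ratio of 67.1 (95% counting interval 22.5 to 329), and the flowering gene SOC1 (AT2G45660) rose from 8.90 ± 0.693 to 29.4 ± 2.16 CPM (log2 1.72 ± 0.13, adjusted p = 4.82e-10). The fibre switch NST1 (AT2G46770, 0.11 ± 0.27, adjusted p = 0.774) did not pass at day 1, nor did its partner SND1 (AT1G32770, 1.65 ± 0.84, adjusted p = 0.122), which passed with DESeq2 (1.78, adjusted p = 0.00877) or without induced day 0 replicate 1 (3.3, adjusted p = 0.035). The secondary wall cellulose synthase gene CESA4 (AT5G44030) did not pass (-0.04 ± 0.23, adjusted p = 0.905).

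The phloem list had 8 of 15 genes down (9 down adjusted over the list alone) at day 1, and camera's set test gave adjusted p = 0.00378, but adjusted p = 0.607 with an estimated correlation. The sucrose loader gene SUC2 (AT1G22710, -1.05 ± 0.15) and the phloem regulators SMXL3 (AT3G52490, -1.90 ± 0.18) and SMXL4 (AT4G29920, -1.45 ± 0.17) fell. The periderm and suberin list had 9 of 12 genes down (the same adjusted over the list alone, median -0.93, adjusted p = 0.0134, but adjusted p = 0.704 with an estimated correlation), with GPAT5 (AT3G11430, -1.1 ± 0.23) and the fatty acid hydroxylase gene CYP86A1 (AT5G58860, -1.04 ± 0.20) among those that fell. The photosynthesis list had 16 of 21 genes down (1 up and 18 down adjusted over the list alone), with a median of -1.04 (adjusted p = 0.00185, but adjusted p = 0.704 with an estimated correlation), including the antenna genes LHCA2 (AT3G61470, -1.05 ± 0.20) and LHCB5 (AT4G10340, -1.06 ± 0.19). Summed over the 21 measured photosynthesis genes, the induced day 0 libraries stood at 9404, 4631 and 7153 CPM and the day 1 libraries at 3567, 3776 and 3365 CPM.

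The following lists did not pass the set test at day 1. The jasmonate list had 4 of 14 genes up (the same adjusted over the list alone, adjusted p = 0.0502), and the repressor gene JAZ9 (AT1G70700) rose by 2.42 ± 0.43. The auxin list had 5 of 10 genes up and 1 down (the same adjusted over the list alone, adjusted p = 0.0502). IAA19 (AT3G15540) changed by 2.24 ± 0.26. The cambium list had 3 of 19 genes up and 10 down (the same adjusted over the list alone, adjusted p = 0.0502), where SMXL5 (AT5G57130, -1.63 ± 0.12) and the growth regulator ANT (AT4G37750, -0.94 ± 0.12) fell and the stem cell regulator WOX4 (AT1G46480) rose (0.71 ± 0.13). The gibberellin list had 4 of 24 genes up and 9 down (4 up and 10 down adjusted over the list alone, adjusted p = 0.0891), and the synthesis gene KAO2 (AT2G32440) fell by 1.45 ± 0.14. The lignin list was split, with 3 of 23 genes up and 10 down (3 up and 11 down adjusted over the list alone, adjusted p = 0.0891). C4H (AT2G30490), early in the phenylpropanoid pathway, fell (-1.12 ± 0.16) and the peroxidase gene PRX64 (AT5G42180) rose (2.43 ± 0.40). The salicylate list had 4 of 11 genes down (the same adjusted over the list alone, adjusted p = 0.22), with the synthesis gene ICS1 (AT1G74710, -1.47 ± 0.23) down. The heat shock list had 3 of 6 genes up (the same adjusted over the list alone, adjusted p = 0.137). The primary wall list had 5 of 12 genes up and 3 down (the same adjusted over the list alone, adjusted p = 0.689); the median of the latter was above 0 and its mean below. The root hair list, with 2 measured members, gave adjusted p = 0.84.

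ABA genes moved both ways at day 1. The ABA response list had 8 of 25 genes up and 4 down (8 up and 5 down adjusted over the list alone, adjusted p = 0.445), in which the kinase gene MAPKKK18 (AT1G05100, 1.54 ± 0.24) and HB12 (AT3G61890, 1.00 ± 0.13) rose and HB7 (AT2G46680, -0.85 ± 0.13) fell. ABA synthesis and turnover had 3 of 12 genes up and 3 down (the same adjusted over the list alone, adjusted p = 0.445), with ABA2 (AT1G52340) up (0.66 ± 0.10), ABA4 (AT1G67080) down (-1.23 ± 0.18) and the catabolic gene CYP707A4 (AT3G19270) up (1.81 ± 0.27). NCED3 (AT3G14440), the rate-limiting step under drought, did not pass (1.35 ± 0.68, adjusted p = 0.118), but did with only the libraries compared in the model (1.35, adjusted p = 0.0496). The ABA receptor list had 2 of 11 genes up (1 up adjusted over the list alone, adjusted p = 0.689). In all, 8108 of 19833 genes changed at day 1, 3861 up and 4247 down, and 724 rose and 1295 fell by at least 2-fold. Among the largest rises were LEA3 (AT1G02820, 0.427 ± 0.219 to 132 ± 14.4 CPM) and the sugar exporter gene SWEET15 (AT5G13170, at least 170-fold), and among the largest falls the ethylene and jasmonate regulator ORA59 (AT1G06160, -3.67 ± 0.45) and MYB82 (AT5G52600, -3.84 ± 0.35).

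At day 2 the first fibre regulators had risen. SND1 rose by 3.34 ± 0.65 to 3.33 ± 0.808 CPM (adjusted p = 0.00025) and NST1 by 1.25 ± 0.24 to 8.95 ± 0.939 CPM (adjusted p = 0.000202), while the vessel switches VND7 (AT1G71930, -1.31 ± 0.26) and VND6 (AT5G62380, -0.81 ± 0.17) fell. CESA4 had not passed the test (-0.23 ± 0.23, adjusted p = 0.436). FT stood at 30.7 ± 24.5 CPM, at least 542-fold above day 0, and SOC1 had risen by 2.07 ± 0.13. The phosphate-starvation RNA IPS1 (AT3G09922) rose by a pooled ratio of 1550 (95% counting interval 277 to 61100).

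Phloem genes fell as a group at day 2, with 1 of 15 genes up and 12 down (the same adjusted over the list alone, median -0.72, adjusted p = 0.000858, but adjusted p = 0.612 with an estimated correlation), among them the phloem identity gene APL (AT1G79430, -0.80 ± 0.11) and CALS7 (AT1G06490, -0.80 ± 0.15). The secondary wall regulator list had 2 of 26 genes up and 12 down (the same adjusted over the list alone, adjusted p = 0.133). The xylan list had 2 of 20 genes up and 2 down (1 up and 2 down adjusted over the list alone, adjusted p = 0.621). The defence genes PR2 (AT3G57260, 3.18 ± 0.83) and PR5 (AT1G75040, 3.93 ± 0.92) rose. SPL4 (AT1G53160), which promotes flowering with age (-2.53 ± 0.28), ARR16 (AT2G40670) of the cytokinin response (-2.72 ± 0.57), the stress and ABA response gene RD29A (AT5G52310, -2.49 ± 0.34) and the expansin gene EXPA1 (AT1G69530, -1.29 ± 0.16) fell. PRX64 rose by 4.35 ± 0.40 and IAA19 by 2.65 ± 0.26. Of all genes, 8003 changed, 3796 up and 4207 down, with 762 up and 928 down by at least 2-fold. With only the 6 libraries compared in the model, 5081 genes changed.

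By day 3 SND1, NST1 and the cellulose synthase genes of the secondary wall had risen. SND1 reached 27.3 ± 6.42 CPM from 0.302 ± 0.357 (log2 6.37 ± 0.50, adjusted p = 1.63e-09) and NST1 reached 40.5 ± 12.7 from 3.77 ± 0.944 CPM (log2 3.42 ± 0.22, adjusted p = 5.78e-11). MYB46 (AT5G12870), a direct target of both, rose by 1.39 ± 0.17, and CESA4, CESA7 (AT5G17420) and CESA8 (AT4G18780) rose by 1.62 ± 0.23, 1.65 ± 0.20 and 1.49 ± 0.17. Of the vessel cell death genes, the protease gene XCP1 (AT4G35350, -0.56 ± 0.12) and the nuclease genes BFN1 (AT1G11190, -0.82 ± 0.14) and RNS3 (AT1G26820, -0.99 ± 0.14) fell.

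Xylan synthesis had 18 of 20 genes up (19 up and 1 down adjusted over the list alone) at day 3, with a median of 0.93 (adjusted p = 5.09e-12, but adjusted p = 0.148 with an estimated correlation), and IRX9 (AT2G37090, 1.15 ± 0.16), IRX14L (AT5G67230, 1.51 ± 0.19) and the acetylation gene RWA3 (AT2G34410, 0.98 ± 0.13) rose. The secondary wall cellulose list had 8 of 10 genes up and 1 down (the same adjusted over the list alone, median 1.44, adjusted p = 6.9e-07, but adjusted p = 0.174 with an estimated correlation). The arabinogalactan protein gene FLA12 (AT5G60490) changed by 2.11 ± 0.18. The regulator list had 11 of 26 genes up and 5 down (the same adjusted over the list alone, adjusted p = 0.000875, but adjusted p = 0.28 with an estimated correlation). C3H14 (AT1G66810) changed by 1.69 ± 0.20. Vessel cell death had 4 of 5 genes down (the same adjusted over the list alone, adjusted p = 0.00352, but adjusted p = 0.28 with an estimated correlation). Repressors of the secondary wall had 5 of 7 genes up (the same adjusted over the list alone, adjusted p = 0.0216, but adjusted p = 0.305 with an estimated correlation). MYB4 (AT4G38620) changed by 1.01 ± 0.15. Lignin genes, with 8 of 23 genes up and 2 down (9 up and 2 down adjusted over the list alone), missed the set test (adjusted p = 0.0545), although PRX64 rose by 7.22 ± 0.43 to 861 ± 178 CPM and LAC4 (AT2G38080), a laccase gene of lignin polymerisation, by 0.78 ± 0.20.

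The cell division list had 2 of 13 genes up and 8 down (the same adjusted over the list alone, adjusted p = 0.02, but adjusted p = 0.641 with an estimated correlation). The cytokinesis gene KN (AT1G08560) changed by -0.71 ± 0.12. The cytokinin response list had 5 of 7 genes down (6 down adjusted over the list alone, adjusted p = 0.00143, but adjusted p = 0.148 with an estimated correlation). ARR16 changed by -3.38 ± 0.63. The gibberellin list had 3 of 24 genes up and 10 down (the same adjusted over the list alone, adjusted p = 0.0417, but adjusted p = 0.148 with an estimated correlation), with KAO2 at -1.62 ± 0.14 and the receptor gene GID1B (AT3G63010) at -1.23 ± 0.22. Phloem genes had 2 of 15 genes up and 10 down (the same adjusted over the list alone, adjusted p = 0.00143, but adjusted p = 0.28 with an estimated correlation). Periderm genes had 11 of 12 genes down (the same adjusted over the list alone, adjusted p = 0.000467, but adjusted p = 0.405 with an estimated correlation). Photosynthesis genes had 11 of 21 genes down (13 down adjusted over the list alone, adjusted p = 0.006, but adjusted p = 0.757 with an estimated correlation). The auxin list had 4 of 10 genes up (5 up and 1 down adjusted over the list alone, adjusted p = 0.0454, but adjusted p = 0.405 with an estimated correlation). COR15A (AT2G42540), a cold and ABA response gene (-3.46 ± 0.50), and the Calvin cycle gene GAPB (AT1G42970, -3.94 ± 0.66) fell. At this day 7410 genes changed, 3613 up and 3797 down, of which 738 and 1036 by at least 2-fold.

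At day 4 SND1 stood at 39.4 ± 11.9 CPM (log2 6.90 ± 0.49, adjusted p = 2.33e-10) and NST1 at 48.4 ± 9.94 CPM (3.68 ± 0.22). CESA4 rose from 166 ± 15.8 to 703 ± 285 CPM (2.09 ± 0.23, adjusted p = 1.99e-07), with CESA7 and CESA8 at 2.09 ± 0.20 and 1.92 ± 0.17. KNAT7 (AT1G62990), a wall regulator, rose by 1.07 ± 0.11 and COBL4 (AT5G15630), needed for cellulose in secondary walls, by 2.07 ± 0.22. The floral gene FUL (AT5G60910), with only 192 counts over all 33 libraries, rose (2.88 ± 0.68), and FT stood at 8.2 ± 0.935 CPM, at least 137-fold above day 0.

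The xylan list had 18 of 20 genes up (18 up and 1 down adjusted over the list alone, median 1.28, adjusted p = 1.05e-17, but adjusted p = 0.118 with an estimated correlation). The cellulose list had 8 of 10 genes up and 1 down (the same adjusted over the list alone, median 1.99, adjusted p = 1.74e-09, but adjusted p = 0.146 with an estimated correlation). The regulators had 14 of 26 genes up and 2 down (15 up and 2 down adjusted over the list alone, adjusted p = 6.43e-06, but adjusted p = 0.163 with an estimated correlation). Lignin genes passed the set test, with 8 of 23 genes up and 2 down (the same adjusted over the list alone, adjusted p = 0.00641, but adjusted p = 0.576 with an estimated correlation), among them the laccase genes LAC4 (1.33 ± 0.20) and LAC17 (AT5G60020, 0.95 ± 0.14) and PRX64 at 1089 ± 261 CPM. Vessel cell death genes had 4 of 5 genes down (the same adjusted over the list alone, adjusted p = 0.0306, but adjusted p = 0.517 with an estimated correlation). Phloem had 12 of 15 genes down (1 up and 12 down adjusted over the list alone, adjusted p = 0.00449, but adjusted p = 0.344 with an estimated correlation). Periderm had 8 of 12 genes down (9 down adjusted over the list alone, adjusted p = 0.00868, but adjusted p = 0.576 with an estimated correlation). Cytokinin response had 6 of 7 genes down (the same adjusted over the list alone, adjusted p = 0.00641, but adjusted p = 0.163 with an estimated correlation). Cell division had 1 of 13 genes up and 8 down (2 up and 9 down adjusted over the list alone, adjusted p = 0.0134, but adjusted p = 0.576 with an estimated correlation). The gibberellin synthesis genes KAO2 (-1.67 ± 0.14) and GA3 (AT5G25900, -1.06 ± 0.08) fell. Wall repressors passed upward as a set too (median 0.54, adjusted p = 0.0134, but adjusted p = 0.298 with an estimated correlation). Of all genes 8011 changed, 3943 up and 4068 down, 840 and 1227 of them by at least 2-fold. PRX64 (7.56 ± 0.44) was among the largest rises.

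SND1, NST1 and the cellulose synthase genes also stood above day 0 at day 6, which no control day matches. SND1 reached 106 ± 18.5 CPM (log2 8.33 ± 0.48, adjusted p = 1.99e-12) and NST1 85 ± 15.7 CPM (4.50 ± 0.23). CESA4 rose to 1933 ± 332, CESA7 to 1290 ± 195 and CESA8 to 1165 ± 181 CPM, by 3.54 ± 0.25, 3.19 ± 0.21 and 3.16 ± 0.18. LAC4 rose by 2.72 ± 0.21, and the monolignol gene CAD4 (AT3G19450) by 2.17 ± 0.16.

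The xylan list had 18 of 20 genes up (19 up adjusted over the list alone) at day 6 with a median of 2.19 (adjusted p = 6.05e-41, and adjusted p = 0.00155 with an estimated correlation). Lignin had 19 of 23 genes up and 1 down (the same adjusted over the list alone) with a median of 1.41 (adjusted p = 1.43e-24, and adjusted p = 0.00971 with an estimated correlation). Cellulose had 9 of 10 genes up and 1 down (the same adjusted over the list alone) with a median of 3.09 (adjusted p = 5.43e-22, and adjusted p = 0.00252 with an estimated correlation). The regulators had 18 of 26 genes up and 2 down (the same adjusted over the list alone) with a median of 2.05 (adjusted p = 8.69e-21, and adjusted p = 0.00155 with an estimated correlation). Among them MYB43 (AT5G16600) rose by 2.27 ± 0.14 and KNAT7 by 2.00 ± 0.11. The repressor list had 5 of 7 genes up (the same adjusted over the list alone, adjusted p = 0.000228, but adjusted p = 0.0878 with an estimated correlation). WRKY12 (AT2G44745) changed by 1.91 ± 0.16. Periderm had 11 of 12 genes down (the same adjusted over the list alone, median -1.18, adjusted p = 1.2e-06, but adjusted p = 0.239 with an estimated correlation). Cell division had 9 of 13 genes down (the same adjusted over the list alone, adjusted p = 0.00707, but adjusted p = 0.445 with an estimated correlation). SPL4 fell from 15.0 ± 2.86 to 0.384 ± 0.0907 CPM. The floral organ gene SEP2 (AT3G02310) rose by a pooled ratio of 38.0 (95% counting interval 12.4 to 189), in a list with 2 of 3 genes up (the same adjusted over the list alone, adjusted p = 0.294). ABA response had 8 of 25 genes up and 11 down (9 up and 11 down adjusted over the list alone, adjusted p = 0.345), with the cold and ABA genes KIN1 (AT5G15960, -2.96 ± 0.26) and KIN2 (AT5G15970, -2.69 ± 0.23) down, while SNRK2.6 (AT4G33950), the kinase gene of ABA signalling, rose by 1.46 ± 0.14. Auxin passed upward as a set too (median 0.93, adjusted p = 0.00685, but adjusted p = 0.239 with an estimated correlation). Photosynthesis and flavonoid synthesis passed downward as sets too (medians -0.56 and -1.35, adjusted p = 0.013 and 0.013, but adjusted p = 0.689 and 0.445 with an estimated correlation). Of all genes 8017 changed, 3972 up and 4045 down, 1015 and 1213 of them by at least 2-fold.

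Day 14 differed from day 0 in more genes than any earlier day. SND1 stood at 122 ± 4.14 CPM (log2 8.54 ± 0.47, adjusted p = 2.07e-13), CESA4 had risen by 3.74 ± 0.25 and LAC4 by 3.03 ± 0.22, and the lignin gene CCoAOMT1 (AT4G34050) by 2.18 ± 0.14. The senescence protease gene SAG12 (AT5G45890) rose by 8.22 ± 0.45 and SAG13 (AT2G29350) by 2.54 ± 0.35. The mitotic cyclin gene CYCB1;1 (AT4G37490, -1.84 ± 0.19) and the chalcone synthase gene CHS (AT5G13930, -5.62 ± 1.05) fell. SOC1 stood at 139.6 ± 8.09 CPM (3.97 ± 0.14), FUL had risen by 4.02 ± 0.65 and AP1 (AT1G69120) by 2.94 ± 0.37, and FT stood at 33.1 ± 23.8 CPM.

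The lignin list had 20 of 23 genes up (the same adjusted over the list alone, median 2.38, adjusted p = 5.92e-22, and adjusted p = 0.0312 with an estimated correlation). Xylan had 17 of 20 genes up and 1 down (the same adjusted over the list alone, median 2.12, adjusted p = 3.92e-17, and adjusted p = 0.0379 with an estimated correlation). Cellulose had 8 of 10 genes up (9 up adjusted over the list alone, median 3.21, adjusted p = 1.51e-11, and adjusted p = 0.0379 with an estimated correlation). The regulators had 19 of 26 genes up and 4 down (20 up and 4 down adjusted over the list alone, median 2.37, adjusted p = 4.43e-12, and adjusted p = 0.0312 with an estimated correlation). MYB85 (AT4G22680), a lignin regulator, rose by 4.33 ± 0.23 and the xylan gene GAUT12 (AT5G54690) by 3.12 ± 0.18. Cell division had 13 of 13 genes down (the same adjusted over the list alone, median -1.53, adjusted p = 1.01e-11, and adjusted p = 0.043 with an estimated correlation). Cambium had 4 of 19 genes up and 10 down (the same adjusted over the list alone, adjusted p = 0.0134, but adjusted p = 0.198 with an estimated correlation). Flavonoid synthesis had 9 of 9 genes down (the same adjusted over the list alone, median -3.73, adjusted p = 0.00406, but adjusted p = 0.352 with an estimated correlation). The senescence list had 6 of 10 genes up and 1 down (7 up and 1 down adjusted over the list alone, median 1.34, adjusted p = 0.0134, but adjusted p = 0.0797 with an estimated correlation). The clock list had 8 of 11 genes up and 3 down (the same adjusted over the list alone, median 0.73, adjusted p = 0.0134, and adjusted p = 0.043 with an estimated correlation), with GI (AT1G22770) at 1.59 ± 0.18. Photosynthesis had 18 of 21 genes down (the same adjusted over the list alone, adjusted p = 0.00406, but adjusted p = 0.562 with an estimated correlation), and the photoprotection gene PSBS (AT1G44575) fell by 7.31 ± 0.92.

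The ABA receptors and kinases had 6 of 11 genes up and 2 down (7 up and 2 down adjusted over the list alone, adjusted p = 0.03, but adjusted p = 0.172 with an estimated correlation), and SNRK2.6 rose from 8.31 ± 1.71 to 84.9 ± 5.87 CPM. ABA synthesis had 3 of 12 genes up and 2 down (the same adjusted over the list alone, adjusted p = 0.816). ABA response had 10 of 25 genes up and 8 down (11 up and 8 down adjusted over the list alone, adjusted p = 0.911), with a median above 0 and a mean below. In the latter ABF2 (AT1G45249) rose (1.04 ± 0.08), KIN2 fell from 614 ± 71.6 to 31.6 ± 12.3 CPM and COR15A had no counts left, at least 158-fold lower. The gibberellin gene GA20OX2 (AT5G51810) rose by 5.36 ± 0.63 and KAO2 fell by 2.32 ± 0.15. Wall repressors and auxin passed upward as sets too (medians 0.89 and 1.63, adjusted p = 0.00406 and 0.0395, but adjusted p = 0.143 and 0.352 with an estimated correlation). Periderm passed downward as a set too (median -1.13, adjusted p = 0.0041, but adjusted p = 0.401 with an estimated correlation). In all 12349 genes changed, 6081 up and 6268 down, 1987 and 2330 of them by at least 2-fold. Without control libraries of days 2, 6 and 14, the changes of those days include those of age.

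An F test over the 6 later days asked which genes changed at any time in the induced line, and called 16147 of 19833. Without day 14 in the test, chosen after the data were seen, it called 12474.

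**Figure D2:**
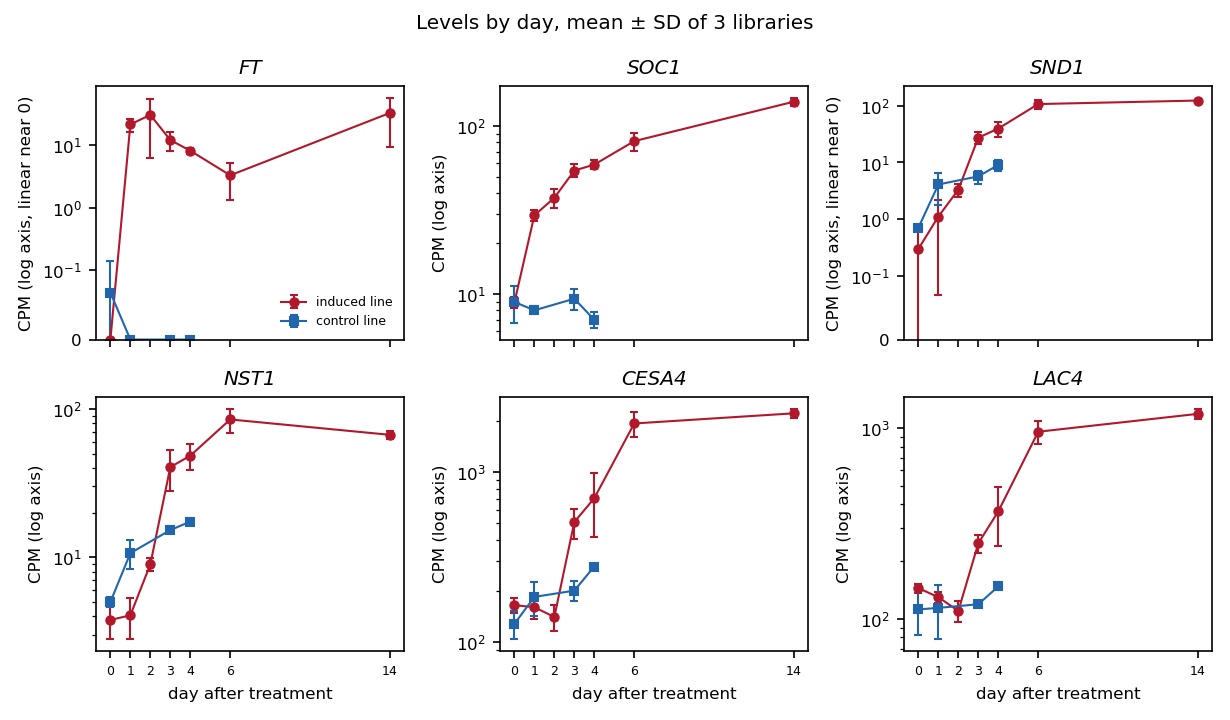
Mean CPM ± SD (3 libraries) on a log axis (linear near 0 for FT and SND1) by day for FT, SOC1, SND1, NST1, CESA4 and LAC4, with circles for the induced line and squares for the control line. FT and SOC1 are up by day 1 in the induced line, SND1 and NST1 from day 2, and CESA4 from day 3.

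**Figure D3:**
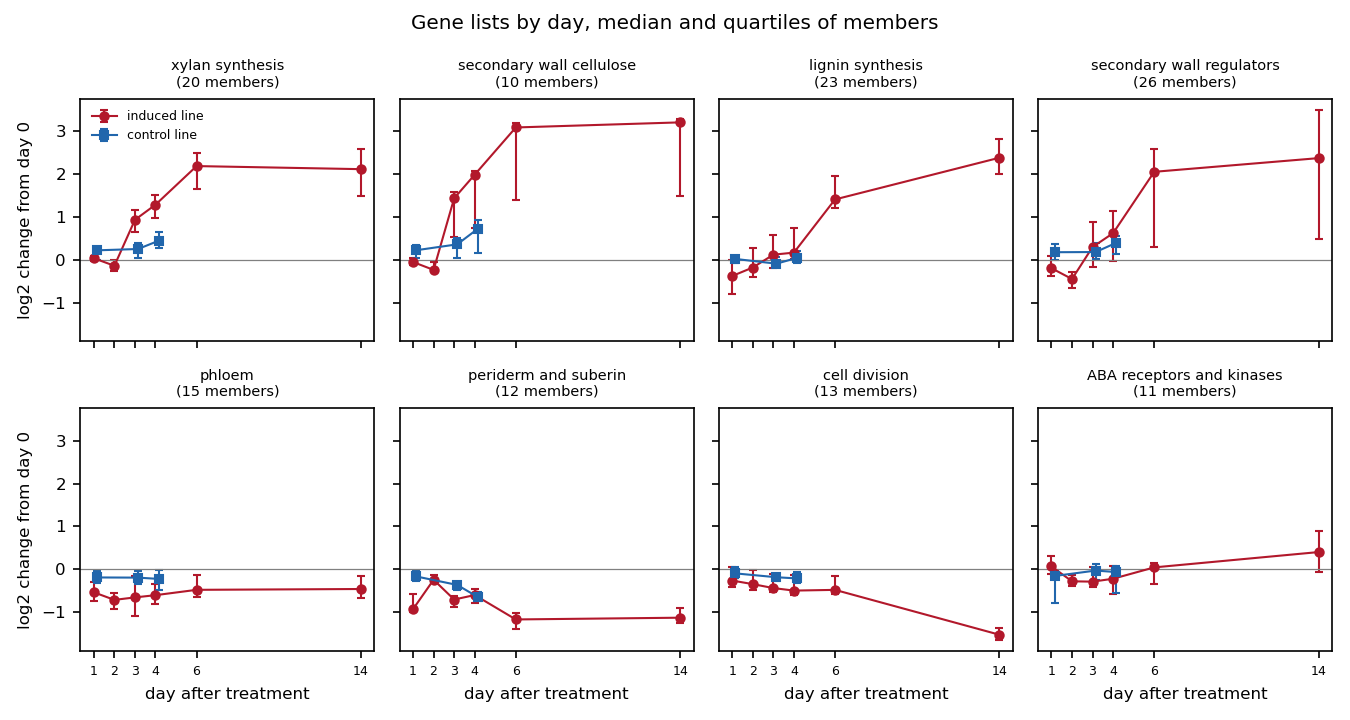
Median log2 change against day 0 of the measured members of 8 gene lists by day, circles for the induced line and squares for the control line, with bars from the lower to the upper quartile of the members. The xylan list reaches 2.19 at induced day 6 and 0.44 at control day 4.

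The control line showed how plants given water changed over the same days. At day 1 SND1 rose by 2.54 ± 0.55 to 4.11 ± 2.33 CPM (adjusted p = 0.00627; without control day 1 replicate 1, 1.99, adjusted p = 0.0527), NST1 by 1.1 ± 0.23 and PRX64 by 2.46 ± 0.36. The ABA receptor genes PYL6 (AT2G40330, -1.47 ± 0.21) and PYR1 (AT4G17870, -0.73 ± 0.16) fell, and the clock gene GI rose (1.09 ± 0.19). The ABA receptor list had 4 of 11 genes down (the same adjusted over the list alone, adjusted p = 0.00392, but adjusted p = 0.225 with an estimated correlation). Auxin had 2 of 10 genes up (5 up adjusted over the list alone, adjusted p = 0.000588, but adjusted p = 0.231 with an estimated correlation). Cambium had 3 of 19 genes up (4 up adjusted over the list alone, adjusted p = 0.0239, but adjusted p = 0.591 with an estimated correlation). The cyclin gene CYCD3;1 (AT4G34160) changed by 0.46 ± 0.08. The secondary wall regulators had 2 of 26 genes up (the same adjusted over the list alone, adjusted p = 0.0141, but adjusted p = 0.613 with an estimated correlation). Xylan and flavonoid synthesis passed upward as sets too (medians 0.22 and 1.06, adjusted p = 0.0239 and 0.0141, but adjusted p = 0.751 and 0.613 with an estimated correlation). Of the flavonoid genes, 5 were up adjusted over the list alone. Phloem had 2 of 15 genes down (the same adjusted over the list alone, adjusted p = 0.0308, but adjusted p = 0.613 with an estimated correlation). Photosynthesis passed downward as a set too (median -0.22, adjusted p = 0.0141, but adjusted p = 0.768 with an estimated correlation). Of all genes 1352 changed, 638 up and 714 down, 76 and 103 by at least 2-fold. The count was 788 without control day 0 replicate 1, 851, 647 and 859 without control day 1 replicate 1, 2 or 3, and 674 with only the 6 libraries compared.

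By day 3 some stress, jasmonate and fibre genes had risen in the control line. The heat stress regulator HSFA2 (AT2G26150) rose by 4.14 ± 1.01, but not without control day 3 replicate 1 (1.79, adjusted p = 0.315), control day 0 replicate 1 (3.95, adjusted p = 0.0677) or 3 (3.79, adjusted p = 0.0516), nor with only the libraries compared (4.14, adjusted p = 0.26). The anthocyanin regulators MYB113 (AT1G66370) and PAP1 (AT1G56650) rose by 4.02 ± 0.85 and 1.62 ± 0.35. SND1 rose by 2.98 ± 0.53 (adjusted p = 0.00159), and NST1 by 1.60 ± 0.23, while CESA4 did not pass (0.65 ± 0.23, adjusted p = 0.0863), though it did with DESeq2 (0.65, adjusted p = 0.0389). The jasmonate list had 3 of 14 genes up (8 up adjusted over the list alone, adjusted p = 0.000182, but adjusted p = 0.474 with an estimated correlation). Heat shock had 3 of 6 genes up (5 up adjusted over the list alone, adjusted p = 0.00719, but adjusted p = 0.474 with an estimated correlation). Auxin had 3 of 10 genes up (6 up adjusted over the list alone, adjusted p = 3e-05, but adjusted p = 0.0987 with an estimated correlation). ABA synthesis and turnover had 2 of 12 genes up (4 up adjusted over the list alone, adjusted p = 0.00719, but adjusted p = 0.0987 with an estimated correlation). The secondary wall regulators had 3 of 26 genes up (the same adjusted over the list alone, adjusted p = 0.00283, but adjusted p = 0.474 with an estimated correlation). Xylan had 2 of 20 genes up and 1 down (6 up and 1 down adjusted over the list alone, adjusted p = 0.00283, but adjusted p = 0.474 with an estimated correlation). Cambium had 5 of 19 genes up (the same adjusted over the list alone, adjusted p = 0.0319, but adjusted p = 0.474 with an estimated correlation). Flavonoid synthesis had 2 of 9 genes up (4 up adjusted over the list alone, adjusted p = 0.00514, but adjusted p = 0.474 with an estimated correlation). Senescence had 1 of 10 genes up (the same adjusted over the list alone, adjusted p = 0.0319, but adjusted p = 0.442 with an estimated correlation). Cellulose was up as a set (median 0.36, adjusted p = 0.0152, but adjusted p = 0.474 with an estimated correlation). Photosynthesis and cell division were down as sets (medians -0.47 and -0.19, adjusted p = 6.69e-05 and 0.0194, but 0.474 and 0.501 with an estimated correlation). Periderm had 1 of 12 genes down (5 down adjusted over the list alone, adjusted p = 0.000332, but adjusted p = 0.474 with an estimated correlation). Phloem had 1 of 15 genes down (the same adjusted over the list alone, adjusted p = 0.0435, but adjusted p = 0.477 with an estimated correlation). The counts were 1406 genes, 768 up and 638 down, 128 and 92 by at least 2-fold. They came to 732 without control day 0 replicate 1, 623, 916 and 684 without control day 3 replicate 1, 2 or 3, and 694 with only the 6 libraries compared.

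By day 4 SND1, NST1 and the cellulose synthase genes had risen in the control line too. SND1 rose by 3.67 ± 0.50 to 9.04 ± 1.99 CPM (adjusted p = 6.17e-05), NST1 by 1.79 ± 0.23 to 17 ± 0.689 CPM, and CESA4, CESA7 and CESA8 by 1.12 ± 0.23, 0.92 ± 0.20 and 0.79 ± 0.17. The cellulose gene COBL4 rose by 0.94 ± 0.22, the wall regulator MYB103 (AT1G63910) by 1.81 ± 0.32 and PRX64 from 13.3 ± 3.99 to 156 ± 11.7 CPM. SPL4 fell by 2.32 ± 0.29. SOC1 did not pass (-0.33 ± 0.15, adjusted p = 0.158), but did without control day 0 replicate 1 (-0.52, adjusted p = 0.0269).

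The xylan list had 11 of 20 genes up (13 up and 1 down adjusted over the list alone, median 0.44, adjusted p = 2.59e-07, but adjusted p = 0.236 with an estimated correlation). Cellulose had 5 of 10 genes up (6 up adjusted over the list alone, median 0.72, adjusted p = 3.98e-06, but adjusted p = 0.236 with an estimated correlation). The regulators had 6 of 26 genes up (7 up adjusted over the list alone, adjusted p = 3.98e-06, but adjusted p = 0.236 with an estimated correlation). Periderm had 9 of 12 genes down (10 down adjusted over the list alone, adjusted p = 2.98e-07, but adjusted p = 0.236 with an estimated correlation). Photosynthesis had 5 of 21 genes down (13 down adjusted over the list alone, adjusted p = 2.98e-07, but adjusted p = 0.409 with an estimated correlation). ABA synthesis and turnover had 2 of 12 genes up (the same adjusted over the list alone, adjusted p = 0.0453, but adjusted p = 0.236 with an estimated correlation). The catabolic gene CYP707A2 (AT2G29090) rose (1.29 ± 0.24). Cambium and auxin passed upward as sets too (medians 0.13 and 0.47, adjusted p = 0.025 and 0.00186, but adjusted p = 0.349 and 0.236 with an estimated correlation). Cell division passed downward as a set too (median -0.22, adjusted p = 0.0132, but adjusted p = 0.55 with an estimated correlation). Of all genes 2138 changed, 1120 up and 1018 down, 116 and 260 by at least 2-fold. The count was 1225 without control day 0 replicate 1, and 824, 1283 and 1127 without control day 4 replicate 1, 2 or 3. Across genes, the changes of days 1, 3 and 4 in the induced line correlated with those in the control line at a Pearson r of 0.306, 0.455 and 0.513, genes not being independent replicates. These comparisons share no library. On day 4, 607 genes rose in both lines against 222.7 if the calls were independent, 665 fell in both against 208.8, and 99 went opposite ways.

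**Figure D4:**
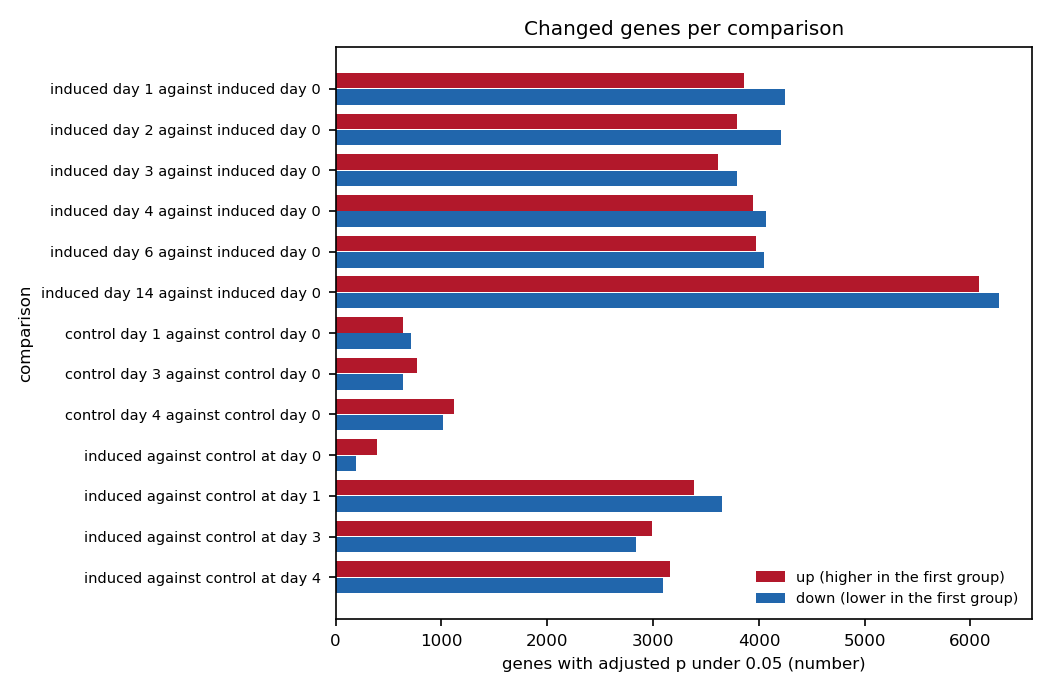
Number of genes higher (up) and lower (down) with adjusted p under 0.05 in each comparison of 2 groups, as bars from 0. Induced day 14 has the longest bars, 6081 up and 6268 down, and the lines at day 0 the shortest, 393 up and 188 down.

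The lines were then compared at day 0. Besides CO (7.73 ± 0.42, adjusted p = 1.83e-11), the ABA and cold response genes RD29A (329 ± 35.9 against 84.1 ± 12.0 CPM, 1.97 ± 0.33) and KIN2 (1.28 ± 0.22), which lies near CO, were higher in the induced line, as was ABI1 (AT4G26080), a phosphatase gene of ABA signalling (0.43 ± 0.09). The gibberellin synthesis gene GA3OX1 (AT1G15550) was lower, 21.1 ± 1.79 against 46.7 ± 8.28 CPM (-1.15 ± 0.20, adjusted p = 0.00164). The ABA receptor genes PYL6 (-1.03 ± 0.21) and PYL5 (AT5G05440, -0.93 ± 0.17) were lower, and the clock genes PRR9 (AT2G46790, 2.47 ± 0.45), RVE8 (AT3G09600, 1.93 ± 0.17) and LHY (AT1G01060, 0.76 ± 0.08) higher.

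At day 0 the ABA response list had 8 of 25 genes up (13 up adjusted over the list alone, median 0.40, adjusted p = 1.04e-08, and adjusted p = 0.00569 with an estimated correlation). Vessel cell death had 4 of 5 genes up (5 up adjusted over the list alone, median 0.57, adjusted p = 1.04e-08, and adjusted p = 0.0154 with an estimated correlation), with XCP1 at 0.57 ± 0.12 and BFN1 at 0.76 ± 0.14. The clock list had 3 of 11 genes up (the same adjusted over the list alone, adjusted p = 8.1e-06, and adjusted p = 0.00221 with an estimated correlation). Flowering had 1 of 13 genes up (2 up adjusted over the list alone, adjusted p = 0.000526, and adjusted p = 0.00569 with an estimated correlation), the member up being CO, whose counts include the fusion. Without CO, a test chosen after the data were seen, the list did not pass at day 0 (adjusted p = 0.276). On days 1, 3 and 4 it passed without CO, at 0.0483, 0.0255 and 0.00253 (adjusted p = 0.154, 0.0686 and 0.0301 with an estimated correlation). Xylan and cytokinin response were up as sets (medians 0.27, adjusted p = 0.000203 and 0.00515, but 0.366 and 0.129 with an estimated correlation). The secondary wall regulators had 2 of 26 genes up (8 up adjusted over the list alone, adjusted p = 1.85e-06, but adjusted p = 0.0721 with an estimated correlation). Photosynthesis had 1 of 21 genes down (1 up and 10 down adjusted over the list alone, adjusted p = 4.4e-06, but adjusted p = 0.366 with an estimated correlation). ABA synthesis had 1 of 12 genes up (the same adjusted over the list alone, adjusted p = 0.0267, but adjusted p = 0.0721 with an estimated correlation). Of all genes 581 differed, 393 higher and 188 lower, 93 and 27 by at least 2-fold. The count was 369 without control day 0 replicate 1 and 313 without induced day 0 replicate 2. With only the 6 libraries compared in the model it was 129, and ABI1 (0.43, adjusted p = 0.217), PYL5 (-0.92, adjusted p = 0.2), PYL6 (-1.02, adjusted p = 0.237) and XCP1 (0.57, adjusted p = 0.247) did not pass.

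On day 1 the induced line was set against the control line of the same day. FT was at least 313-fold higher, and SOC1 was higher by 1.88 ± 0.14 (adjusted p = 2.81e-10). The fibre switches were lower than in the control line, with NST1 at -1.40 ± 0.24 and NST2 (AT3G61910) at -1.90 ± 0.44. SND1 was lower (-2.01 ± 0.53, adjusted p = 0.00469), but not without control day 1 replicate 1 (-1.46, adjusted p = 0.0512) or with only the libraries compared (-1.97, adjusted p = 0.0717). Some flavonoid genes were lower, with F3H (AT3G51240) at -4.47 ± 0.81, the transporter gene GSTF12 (AT5G17220) at -4.72 ± 0.85 and PAP1 at -2.18 ± 0.38. The clock genes PRR9 (4.26 ± 0.37) and CCA1 (AT2G46830, 1.54 ± 0.11) were higher.

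Photosynthesis had 1 of 21 genes up and 18 down (the same adjusted over the list alone, median -1.17, adjusted p = 1.08e-05, but adjusted p = 0.663 with an estimated correlation), LHCB3 (AT5G54270, -1.47 ± 0.24) and LHCA3 (AT1G61520, -1.17 ± 0.19) being lower while the rubisco activase gene RCA (AT2G39730) was higher (1.94 ± 0.32). Summed over these genes, the control day 1 libraries stood at 6777, 9374 and 6200 CPM. Flavonoid synthesis had 7 of 9 genes down (the same adjusted over the list alone, median -3.44, adjusted p = 0.000793, but adjusted p = 0.49 with an estimated correlation). Clock had 6 of 11 genes up and 2 down (the same adjusted over the list alone, adjusted p = 1.48e-05, and adjusted p = 0.00194 with an estimated correlation). Flowering had 7 of 13 genes up and 2 down (the same adjusted over the list alone, adjusted p = 0.000793, and adjusted p = 0.00676 with an estimated correlation). ABA response had 11 of 25 genes up and 1 down (13 up and 2 down adjusted over the list alone, adjusted p = 0.00104, but adjusted p = 0.186 with an estimated correlation), with AFP1 (AT1G69260, 2.00 ± 0.21) and MAPKKK18 (1.83 ± 0.25) higher. The cambium list had 3 of 19 genes up and 9 down (the same adjusted over the list alone, adjusted p = 0.00579, but adjusted p = 0.262 with an estimated correlation), with the meristem gene STM (AT1G62360) at -0.74 ± 0.08 and SMXL5 at -1.53 ± 0.12. Lignin genes were split, with 3 of 23 genes up and 10 down (4 up and 12 down adjusted over the list alone, adjusted p = 0.0737), PAL2 (AT3G53260) being higher (1.09 ± 0.17) and C4H lower (-0.99 ± 0.16). Periderm and gibberellin passed downward as sets too (medians -0.78 and -0.24, adjusted p = 0.00889 and 0.0226, but adjusted p = 0.719 and 0.0705 with an estimated correlation). In total 7039 genes differed, 3387 higher and 3652 lower, 673 and 1086 by at least 2-fold.

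On day 3 several fibre and wall genes stood above the control line. SND1 was higher by 2.26 ± 0.34 (adjusted p = 2.02e-05), NST1 by 1.41 ± 0.20, MYB46 by 1.3 ± 0.18 and the lignin regulator MYB58 (AT1G16490) by 1.81 ± 0.24. CESA4, CESA7 and CESA8 were higher by 1.34 ± 0.23, 1.36 ± 0.20 and 1.35 ± 0.17, LAC17 by 1.16 ± 0.15 and PRX64 by 3.05 ± 0.34. SPL4 was lower (-2.11 ± 0.34), as were GA3OX1 (-1.50 ± 0.21) and GID1B (-1.27 ± 0.22). Xylan synthesis had 17 of 20 genes up (the same adjusted over the list alone, median 1.02, adjusted p = 5.78e-16, and adjusted p = 0.0383 with an estimated correlation). Cellulose had 8 of 10 genes up (8 up and 1 down adjusted over the list alone, adjusted p = 1.37e-07, but adjusted p = 0.0895 with an estimated correlation). The regulators had 11 of 26 genes up (14 up and 1 down adjusted over the list alone, adjusted p = 6e-07, but adjusted p = 0.0684 with an estimated correlation). Lignin had 7 of 23 genes up (the same adjusted over the list alone, adjusted p = 0.00155, but adjusted p = 0.55 with an estimated correlation). Flowering had 5 of 13 genes up and 3 down (5 up and 4 down adjusted over the list alone, adjusted p = 0.000266, and adjusted p = 0.00691 with an estimated correlation). Gibberellin had 1 of 24 genes up and 7 down (2 up and 8 down adjusted over the list alone, adjusted p = 0.00318, and adjusted p = 0.0235 with an estimated correlation). Vessel cell death had 1 of 5 genes up and 1 down (the same adjusted over the list alone, adjusted p = 0.902). The ABA catabolic gene CYP707A3 (AT5G45340) was lower (-1.61 ± 0.28), and ABF2 (0.57 ± 0.08) and SNRK2.6 (0.67 ± 0.14) were higher. Wall repressors passed upward as a set too (median 0.32, adjusted p = 0.0255, but adjusted p = 0.38 with an estimated correlation). Photosynthesis, periderm and cell division passed downward as sets (medians -0.78, -0.46 and -0.38, adjusted p = 0.00141, 0.0221 and 0.036). With an estimated correlation all gave 0.67. Cytokinin response and flavonoid synthesis passed downward as sets too (medians -0.34 and -1.50, adjusted p = 0.0309 and 0.0051, but adjusted p = 0.34 and 0.51 with an estimated correlation). Clock had 7 of 11 genes up and 2 down (the same adjusted over the list alone, adjusted p = 0.00318, and adjusted p = 0.0285 with an estimated correlation). In all 5832 genes differed, 2990 higher and 2842 lower, 577 and 574 by at least 2-fold.

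On day 4 SND1 stood at 39.4 ± 11.9 against 9.04 ± 1.99 CPM (2.11 ± 0.31, adjusted p = 1.25e-05), NST1 at 48.4 ± 9.94 against 17 ± 0.689 CPM (1.48 ± 0.19), and CESA8 at 493 ± 176 against 184 ± 3.00 CPM (1.43 ± 0.17). The xylan genes GUX2 (AT4G33330, 1.43 ± 0.17) and IRX14L (1.95 ± 0.18) and the laccase gene LAC17 (1.39 ± 0.15) were higher. FT was at least 117-fold higher, and SOC1 (3.05 ± 0.14) and the floral repressor FLC (AT5G10140, 2.78 ± 0.77) were higher too. FLC had only 245 counts over all 33 libraries. GA3OX1 (-1.78 ± 0.21), the receptor gene ERL1 (AT5G62230, -2.34 ± 0.34) and ORA59 (-3.38 ± 0.44) were lower. The xylan list had 18 of 20 genes up (the same adjusted over the list alone, median 1.16, adjusted p = 5.59e-17, and adjusted p = 0.0453 with an estimated correlation). The regulators had 15 of 26 genes up (16 up adjusted over the list alone, adjusted p = 3.11e-07, but adjusted p = 0.066 with an estimated correlation). Cellulose had 8 of 10 genes up (the same adjusted over the list alone, adjusted p = 3.11e-07, but adjusted p = 0.114 with an estimated correlation). Lignin had 9 of 23 genes up and 1 down (the same adjusted over the list alone, adjusted p = 0.0037, but adjusted p = 0.52 with an estimated correlation). Flowering had 7 of 13 genes up and 2 down (7 up and 3 down adjusted over the list alone, adjusted p = 4.91e-06, and adjusted p = 0.000789 with an estimated correlation). Clock had 6 of 11 genes up and 2 down (the same adjusted over the list alone, adjusted p = 0.0118, and adjusted p = 0.0487 with an estimated correlation). Gibberellin had 2 of 24 genes up and 9 down (the same adjusted over the list alone, adjusted p = 0.00837, and adjusted p = 0.0402 with an estimated correlation). Vessel cell death had 1 of 5 genes up (the same adjusted over the list alone, adjusted p = 0.85), with a median below 0 and a mean above. ABA1 (AT5G67030, 0.63 ± 0.13) and CYP707A1 (AT4G19230, 0.75 ± 0.17) were higher, and CYP707A2 (-1.14 ± 0.24) and CYP707A3 (-1.39 ± 0.29) lower. Wall repressors passed upward as a set too (median 0.39, adjusted p = 0.0313, but adjusted p = 0.393 with an estimated correlation). Cytokinin response and flavonoid synthesis passed downward as sets too (medians -0.48 and -1.98, adjusted p = 0.0291 and 0.00837, but adjusted p = 0.301 and 0.436 with an estimated correlation). In all 6253 genes differed, 3161 higher and 3092 lower, 768 and 650 by at least 2-fold. Days 3 and 4, which share no library, had 2237 higher genes in common against 476.5 if independent, and 2111 lower genes against 443.1. The line and the dexamethasone went together on every day, so these differences separate neither from the other.

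The interaction of line and day sets the change of the induced line from day 0 against that of the control line. At day 1 SOC1 rose by 1.88 ± 0.20 more in the induced line (adjusted p = 7.73e-07), while the cytokinin response gene ARR16 (-2.86 ± 0.74), the flavonoid regulator PAP1 (-2.22 ± 0.52), SMXL5 (-1.51 ± 0.17), ANT (-1.04 ± 0.17) and ORA59 (-4.03 ± 0.57) differed downward. SRG3 (AT3G02040), a phosphate-starvation gene, differed upward by 6.18 ± 0.83, as did the ABA receptor genes PYR1 (1.17 ± 0.22) and PYL1 (AT5G46790, 0.69 ± 0.20), and RD29A differed downward (-1.85 ± 0.46). NST1 did not pass (-0.99 ± 0.35, adjusted p = 0.0523), but did with DESeq2 (-0.98, adjusted p = 0.0222), upper quartile scaling (-1.03, adjusted p = 0.0435), or without control day 1 replicate 1 (-1.09, adjusted p = 0.0447), induced day 0 replicate 2 (-1.19, adjusted p = 0.0241) or induced day 1 replicate 3 (-1.28, adjusted p = 0.0192). The cambium list had 8 of 19 genes down (1 up and 11 down adjusted over the list alone, median -0.35, adjusted p = 0.000319, but adjusted p = 0.252 with an estimated correlation). Flavonoid synthesis had 6 of 9 genes down (7 down adjusted over the list alone, median -2.22, adjusted p = 0.00109, but adjusted p = 0.551 with an estimated correlation). The ABA receptors had 4 of 11 genes up (the same adjusted over the list alone, adjusted p = 0.043, but adjusted p = 0.321 with an estimated correlation). Lignin had 2 of 23 genes up and 5 down (2 up and 9 down adjusted over the list alone, adjusted p = 0.043, but adjusted p = 0.788 with an estimated correlation). Phloem had 4 of 15 genes down (the same adjusted over the list alone, adjusted p = 0.0433, but adjusted p = 0.699 with an estimated correlation). Photosynthesis had 2 of 21 genes down (the same adjusted over the list alone, adjusted p = 0.043, but adjusted p = 0.863 with an estimated correlation). Wall regulators and periderm passed downward as sets too (medians -0.44 and -0.60, adjusted p = 0.043 and 0.0433, but adjusted p = 0.671 and 0.788 with an estimated correlation). Clock passed upward as a set too (median 0.28, adjusted p = 0.043, but adjusted p = 0.252 with an estimated correlation). In total 3804 genes had an interaction, 1823 upward and 1981 downward, 444 and 756 by at least 2-fold.

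By day 3 the interaction included the fibre switches. NST1 rose by 1.82 ± 0.32 (adjusted p = 0.000615) more than in the control line, and SND1 by 3.38 ± 0.96 (adjusted p = 0.0198; without control day 0 replicate 1, 3.31, adjusted p = 0.0607). CESA7 and CESA8 rose by 1.12 ± 0.28 and 1.06 ± 0.24 more, FLA12 by 2.04 ± 0.25 and PRX64 by 4.27 ± 0.53. SPL4 (-2.90 ± 0.42), ARR15 (AT1G74890) of the cytokinin response (-1.23 ± 0.27), the vessel death genes BFN1 (-1.06 ± 0.20) and RNS3 (-0.92 ± 0.20), and the cold and ABA genes RD29A (-2.60 ± 0.46) and KIN2 (-1.83 ± 0.30) differed downward. The xylan list had 9 of 20 genes up (16 up adjusted over the list alone, median 0.68, adjusted p = 1.53e-07, but adjusted p = 0.316 with an estimated correlation). Cellulose had 7 of 10 genes up and 1 down (8 up and 1 down adjusted over the list alone, adjusted p = 0.000133, but adjusted p = 0.354 with an estimated correlation). Lignin had 6 of 23 genes up (the same adjusted over the list alone, adjusted p = 0.0143, but adjusted p = 0.551 with an estimated correlation). Cytokinin response had 4 of 7 genes down (6 down adjusted over the list alone, adjusted p = 0.000409, but adjusted p = 0.191 with an estimated correlation). Vessel cell death had 3 of 5 genes down (the same adjusted over the list alone, adjusted p = 0.000931, but adjusted p = 0.316 with an estimated correlation). At day 0 this list, RD29A and KIN2 exceeded control, and on days 3 and 4 the list did not pass against it. ABA response had 2 of 25 genes up and 5 down (2 up and 7 down adjusted over the list alone, adjusted p = 0.0405, but adjusted p = 0.483 with an estimated correlation). Phloem, gibberellin and flavonoid synthesis passed downward as sets too (medians -0.37, -0.22 and -1.50, adjusted p = 0.0402, 0.0463 and 0.0271, but adjusted p = 0.547, 0.204 and 0.547 with an estimated correlation). The mean of phloem was above 0. The interaction passed for 2787 genes, 1385 upward and 1402 downward, 322 and 491 by at least 2-fold.

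At day 4 NST1 rose by 1.89 ± 0.32, MYB46 by 1.1 ± 0.25 and CESA7 by 1.17 ± 0.28 more than in the control line. SND1 rose by 3.23 ± 0.95 more (adjusted p = 0.0213). Without induced day 0 replicate 1 the value was larger (4.88, adjusted p = 0.00933). It did not pass without control day 0 replicate 1 (3.16, adjusted p = 0.065) or 3 (3.20, adjusted p = 0.0522), or induced day 0 replicate 2 (2.75, adjusted p = 0.0558) or 3 (2.92, adjusted p = 0.0539). The laccase gene LAC17 (0.92 ± 0.21), the xylan genes GUX2 (1.28 ± 0.25) and IRX10 (AT1G27440, 1.15 ± 0.24), and SOC1 (3.06 ± 0.20) differed upward, and GID1B (-1.50 ± 0.29), the ABA response gene ABF3 (AT4G34000, -0.92 ± 0.17) and KIN2 (-1.23 ± 0.30) downward. Xylan genes had 13 of 20 genes up (17 up adjusted over the list alone, median 0.76, adjusted p = 4.14e-09, but adjusted p = 0.28 with an estimated correlation). Cellulose had 8 of 10 genes up and 1 down (the same adjusted over the list alone, adjusted p = 0.000118, but adjusted p = 0.354 with an estimated correlation). The regulators had 6 of 26 genes up and 1 down (7 up and 3 down adjusted over the list alone, adjusted p = 0.0342, but adjusted p = 0.612 with an estimated correlation). Lignin had 7 of 23 genes up (the same adjusted over the list alone, adjusted p = 0.0171, but adjusted p = 0.711 with an estimated correlation). Cytokinin response had 5 of 7 genes down (6 down adjusted over the list alone, adjusted p = 0.000257, but adjusted p = 0.179 with an estimated correlation). Vessel cell death had 3 of 5 genes down (4 down adjusted over the list alone, adjusted p = 0.0166, but adjusted p = 0.402 with an estimated correlation). Cambium and flavonoid synthesis passed downward as sets too (medians -0.32 and -1.56, adjusted p = 0.0197 and 0.0193, but adjusted p = 0.37 and 0.612 with an estimated correlation). The interaction passed for 3168 genes, 1550 upward and 1618 downward, 432 and 520 by at least 2-fold. The interaction did not pass for photosynthesis at days 3 and 4 (adjusted p = 0.724 and 0.526), nor for periderm (0.123 and 0.936). An F test of the interactions of days 1, 3 and 4 together called 5035 genes.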

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

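The tests of antisense counts and the grouping of splits by lines apart or mixed were chosen after the results were seen, and the splits before.

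The change from day 0 differed between the lines, by the interaction test, in 3804 genes at day 1, 2787 at day 3, 3168 at day 4 and 5035 over these days together. Of those at day 1, 3163 passed in the induced line and not in the control line, 119 passed the same way in both, 87 in opposite ways, 196 in the control line and not in the induced line, and 239 in neither.

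Lines were shuffled among the libraries within each day to give 50 splits, the real one included. At day 1, 1 of the 50 splits gave as many genes as the real 3804, and the highest other gave 3724. At day 3 it was 1 of 50, with 863 against the real 2787, and at day 4 it was 1 of 50, with 2571 against 3168. For all days together 2 of 50 splits reached 5035, the highest other giving 5821. A split that mixes the lines on the later day is not like the real one. The 5 splits that left the lines whole on day 1, kept or exchanged, gave up to 3724 genes at day 1 (median 1507), and the 44 that mixed them at most 5. For day 3 the 8 such splits gave up to 863 (median 0) and the 41 others at most 7, and for day 4 the 5 gave up to 2571 (median 64) and the 44 others at most 7. Whole-line splits keep the later day's line difference, so they do not mimic chance, and are too few for a share under 0.05. For the induced time course 1 of 50 splits of the induced libraries reached the real 16147, the highest other giving 4849. The other splits mix libraries of different days in a group, which widens the spread within groups and lowers the count. The share therefore speaks only against days that do not differ at all.

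For comparisons of 3 against 3 libraries there are 10 splits, too few for a share under 0.05, and in each 1 split, the real one, gave the count. The real count and the highest other were 8108 and 1 for induced day 1, 8003 and 358 for day 2, 7410 and 0 for day 3, 8011 and 1 for day 4, 8017 and 0 for day 6 and 12349 and 2 for day 14. In the control line they were 1352 and 1, 1406 and 1, and 2138 and 0 on days 1, 3 and 4. Between the lines they were 581 and 65 at day 0, 7039 and 0 at day 1, 5832 and 0 at day 3, and 6253 and 0 at day 4.

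Antisense counts also passed the test, but exceeded reads outside genes, so part were sense reads of overlapping genes. Of 3785 genes tested, 1223 changed at induced day 14. Of these 532 moved with the sense counts, 222 against and 469 had no sense call. The interaction passed for 143 at day 1 and 110 at day 4. In the control line 30, 35 and 56 changed on days 1, 3 and 4.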

How the results depend on the processing

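The time course without day 14 was chosen after the data were seen, and the other settings before.

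Over all genes given by the naming rule, 18485 of 18989 values kept their direction and side of the threshold under settings other than leaving out a library, 271 lost the call, 215 gained it and 18 reversed. With 1 library left out it was 13819 of 15240, with 1034 lost, 153 gained and 234 reversed. Among genes the text keeps, a choice that favours stable calls, the reversed values were those of CESA4 at induced day 1, which ranged from -0.169 to 0.032 and was above 0 at 0.032, 0.013 and 0.02, and of NST1 at induced day 1, which ranged from -0.181 to 0.269 and was below 0 at -0.086 and -0.181. The cause was not tested. Neither gene passed the test in any of these reversed fits.

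Counts of changed genes stayed within 1.5 times the reported count in 159 of 163 settings. With only the groups compared they came to 5081 at induced day 2, 674 and 694 at control days 1 and 3 and 129 between the lines at day 0, where fewer libraries estimate the spread. With 1 library left out, control day 1 ranged from 647 to 1383, day 3 from 623 to 1281, day 4 from 824 to 1861, and the lines at day 0 from 313 to 645, with fewer libraries in the test. With an estimated correlation 24 list tests passed in place of 147. Without day 14 the time course called 12474 genes. Upper quartile scaling gave 3294 up and 4804 down at induced day 6, and 5220 and 7243 at day 14.

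The replicate number was added as a block, although same-numbered libraries of different groups did not deviate together (mean correlation 0.00520, from -0.377 to 0.238), and 10 of 33 libraries correlated best with their own number. The replicate block gave 8083 genes at induced day 1, 2106 at control day 4, 576 between the lines at day 0 and 3820 for the day 1 interaction, all within 1.5 times the reported counts, and 157 list tests passed in place of 147, with 12 calls changed. Depth limits genes such as FT, TSF and IPS1, whose day 0 groups held 0 to 3 counts and give only bounds or wide ratios.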

Other observations

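The list of phosphate genes and all tests in this part, in the form given, were chosen after the results were seen.

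Most of 19 genes of the phosphate starvation response rose in the induced line on each sampled day from 1 to 6. Of the 19, 17 rose at day 1 with a median of 3.14, 15 rose and 1 fell at day 2, 16 and 1 at day 3, 15 rose at day 4, 14 rose and 1 fell at day 6, and 5 rose and 2 fell at day 14. SPX1, a phosphate sensor gene, went from 8.31 ± 0.940 CPM at day 0 to 451 ± 125 at day 1 (mean ± SD), and the acid phosphatase gene PAP17 from 4.39 ± 2.12 to 342 ± 131. The noncoding RNA AT4 went from 142 ± 19.7 to 1230 ± 203. These genes were chosen after some of them had been seen to change, so the counts describe the pattern and do not test it. PHO2, which starvation lowers, is among the 17 and rose by 0.62, and PHR1, the regulator of this response, did not pass (0.075, adjusted p = 0.373). The interaction at day 1 was upward for 13 of the 19 (median 2.90), at day 3 for 8 (1.73) and at day 4 for 9 (1.77).

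In the control line the median of these genes was 0.225 at day 1, 0.0899 at day 3 and 0.194 at day 4. Between the lines at day 0 it was 0.187. Some were picked for their change, so this cannot test a shared change or a line difference at day 0. Dexamethasone itself, without the fusion protein, stays open, since 0 control libraries received it. A phosphate response to activated CO may be one explanation, as a hypothesis that these data cannot separate from a response to dexamethasone.

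The lines differed in 581 genes at day 0, which a genomic segment that differs between the lines could give side by side. CO is not counted here, since its counts include the fusion. The largest number in any run of 50 neighbouring measured genes was then 8, reached on chromosome 4 and, around CO with KIN1 and KIN2, on chromosome 5, which equals the 95th percentile of 10000 random placements (median 7, highest 13, share 0.181; 9 with CO counted), so a segment stays open. A fixed difference would give a slope of 1, or less, as genes were picked by day 0 values. The slope on day 0 was 0.803 ± 0.0649 (bootstrap SE, 580 genes) for day 1. It was 0.647 ± 0.0629 and 0.75 ± 0.0727 for days 3 and 4. Of the 581 genes, 76.8, 67.3 and 72.6% kept their sign on days 1, 3 and 4. The opposite call was made for 43, 61 and 52, so a fixed part of unknown size is possible. A difference in harvest time between the lines was not tested.

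Photosynthesis genes were lower in the induced line at day 1, with a median of -1.17 (set test adjusted p = 1.08e-05, but adjusted p = 0.663 with an estimated correlation), and 2 of the 21 passed the interaction, downward. A smaller share of green tissue would lower the members alike, and they spread from -4.15 to 1.94, with a heterogeneity of 6.8 per degree of freedom. Without RCA, which adds most to it, the heterogeneity was 2.48, between what a like fall would give and what would exclude it, so this stays open. A line difference already present at day 0 had a median of -0.525 at day 0, whose distance from the midpoint of the day 1 value lay within the quartile range of the members (0.26), so it stays open. No biological explanation was tested.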
